A study of Arabidopsis thaliana with 9 samples.

How the data were processed

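RNA was measured in detached leaves of Arabidopsis thaliana Col-0, a standard laboratory accession. Per the labels, plants were 21 days old, each sample was 10 to 15 leaves, and the leaves lay in MS medium for 48 h in the dark with 10 µM of compound 3, with 10 µM of compound 6, or with 0.05% DMSO as the solvent control. The labels name 3 biological replicates in each of 3 groups, which gives 9 samples, each hybridised to its own Affymetrix array after amplification and biotin labelling of total RNA. P-values below therefore measure the spread between biological replicates of this experiment. Control samples are numbered apart from treated ones in the labels. In every comparison with control, separate handling therefore cannot be told apart from treatment. The samples of each compound also form their own unmixed run of numbers. Any effect of sample order therefore cannot be told apart from the difference between the compounds.

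The deposited values are log2 expression values, 1 per transcript cluster (the array's unit for a gene or transcript) and array. RMA, the R package oligo and limma are named in the submitters' processing notes without a version, and a genome build is not given in the sources used here. RMA subtracts background, equalises the distribution of probe values between arrays and summarises the probes of a transcript cluster. The file does not state the base of the logarithm. Values from 0.132 to 13.9 over 38408 transcript clusters have the range of RMA output on the log2 scale, and log2 was taken as the base, so that each fold change rests on it. No array was left out, and no pair of arrays held identical values. Arrays have no read depth, and the number of arrays limits the precision.

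Gene names came from a table that pairs the array's transcript clusters with genes, updated through the RefSeq gene table of assembly TAIR10.1. That table was used for names and for which genes are neighbours, and no coordinates are given. Of the transcript clusters, 16722 were paired with 1 gene, 759 with several genes, and 20927 are not named here. The 16722 cover 16550 genes, and 16574 of them were found in the RefSeq table. A symbol other than the locus identifier was held by 1762 genes, so most genes carry only their locus identifier. Tests between groups used the 16722 transcript clusters paired with 1 gene. The other clusters enter array medians, some normalizations, the alternative that tests all transcript clusters, and values marked as theirs.

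Each comparison was a contrast of group means in 1 linear model over all 9 arrays, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. With 3 groups of 3 arrays the model has 6 residual degrees of freedom, and the moderation added 7.89 prior degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, two-sided. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p under 0.1, so single genes were tested with the moderated model and not by permutation. Fold changes are 2 to the power of the log2 difference. Where a group's value is dim, as for ARR15 in control leaves at 2.49, the fold is approximate, since signal over background was not measured. Errors beside group values are SDs over 3 arrays, SE is the moderated standard error of a difference, and intervals are 95% confidence intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

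Before the data were examined, 35 gene lists were fixed from textbook knowledge of cytokinin action, photosynthesis, senescence, other hormones, metabolism and cell types, with 755 members. Of these, 133 were measured by a transcript cluster paired with 1 gene, and 6 were dropped because the gene tables gave their locus another name. The 20 lists with at least 3 measured members were tested with camera, limma's competitive set test, at a preset correlation between genes of 0.01, and adjusted over the 20 lists. Camera asks whether the genes of a list moved more in 1 direction than the other genes measured. It was run again with the correlation estimated from each list, and fry, which tests whether the genes of a list moved on balance in 1 direction without comparing them with other genes, was run as an alternative. The interval of a list's mean change uses the variance of that list's mean over the arrays with 6 degrees of freedom. This form replaced one based on moderated variances after the first values had been seen.

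The genes named were set by a rule written before the data were examined. For each compound against control it takes the 10 called genes that rose most and the 10 that fell most, among those with a symbol other than the locus and with all 3 treated arrays on the same side of all 3 control arrays, and 5 and 5 between the compounds. From each list it adds up to 4 called members with the greatest change or, where none was called, up to 2 as values only. A gene with several transcript clusters is represented by the one with the highest mean. A set of markers was to be named whatever its values. Of that set ARR15 and RR16 were measured, and ARR4, ARR5, ARR6, ARR7, CKX4, SAG12, SGR1, ORE1, LHCB2.2, RBCS1A and GLK2 are not analysed here. Among genes the rule selects, examples whose call held whichever array of the groups compared was left out were preferred, a choice made after the values were seen. Genes named by any other route are marked as chosen after their values were seen.

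The comparisons with control share their 3 control arrays. To show what sharing alone produces, 100 pairs of unchanged groups were simulated, each pair with a shared simulated control group. All simulated arrays, controls included, were random mixtures of the measured arrays' deviations from their group means. The controls were too few to be split into parts of at least 2.

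The model was tested on simulated data for compound 3 against control over 16722 transcript clusters. Of 100 genes changed by 1 on the log2 scale 55% were called, of 100 genes changed by 2 all 100% were called, and 7 unchanged genes were called. For compound 6 against control, camera gave an unadjusted p under 0.05 to a simulated list of 10 genes shifted by 0.5, and to 2 of 40 unshifted lists. Genes were simulated independently of each other, whereas correlations estimated in the tested lists reached 0.624. The simulation therefore does not show how often camera errs for correlated lists.

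The alternatives, fixed before the data were examined, were quantile normalization applied again, centring of each array on its median over all transcript clusters, cyclic loess, a filter at the 30th percentile of the mean, all transcript clusters, another variance model (trend and robust), only the 2 groups compared, the replicate number as a block, array weights, a minimum log2 change of 1, averaging of transcript clusters of 1 gene, and leaving out each array of the groups compared in turn. Centring on the median over transcript clusters paired with 1 gene was added after seeing the data.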

Results

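Genome-wide expression was measured in detached, senescing leaves of Arabidopsis Col-0 kept for 48 h in the dark with compound 3, compound 6 or the solvent DMSO alone. The labels describe both compounds as cytokinins, plant hormones that delay leaf senescence, and identify them by code names alone. Each group held 3 biological replicates, and the 9 arrays carried log2 RMA values between 0.132 and 13.9. Over transcript clusters paired with 1 gene the array medians lay between 3.7 and 3.81. Over all transcript clusters they lay between 3.71 and 3.83 on control arrays and between 3.87 and 4.15 on treated arrays. Part of that gap lies in an unbroken run of 7079 unnamed transcript clusters at the start of the table, whose median was 2.3 to 2.44 on control arrays and 2.54 to 3.39 on treated arrays. The design asks which transcripts of a senescing leaf change with each compound, which changes the compounds share, and where the compounds differ. No leaves were measured at the start of the 48 h. Rose, raised and fell therefore mean higher or lower than in control leaves at 48 h. A gain over the starting level cannot be told apart from a slower loss than in control leaves.

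**Figure D1:**
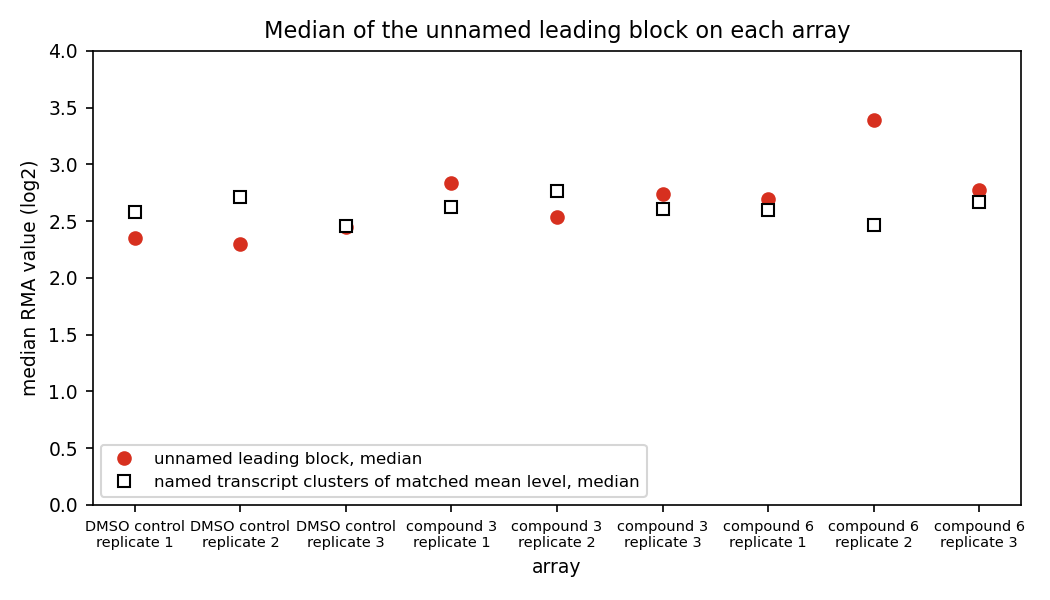
Median log2 RMA value (vertical axis) of 7079 unnamed transcript clusters at the start of the table, as red points, and of named transcript clusters matched to them on mean level, as open squares, on each array (horizontal axis). The red points lie between 2.3 and 2.44 on control arrays and between 2.54 and 3.39 on treated arrays.

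Leaves kept with compound 3 had more transcript of both measured type-A response regulators and of all 3 measured Calvin cycle genes than control leaves, and less of 5 of 11 autophagy genes and 3 of 5 genes that darkness or sugar shortage induces. With an estimated correlation the Calvin cycle, autophagy and dark and carbon starvation lists lost their calls (adjusted p = 0.0523, 0.172 and 0.272). ARR15 (AT1G74890), a type-A response regulator whose transcription cytokinin induces, stood at 7.45 ± 0.26 against 2.49 ± 0.31 in control leaves (log2 value, SD, n = 3), 31.1-fold higher (limma, adjusted p = 1.1e-07). SBPASE (AT3G55800), the sedoheptulose-bisphosphatase of the Calvin cycle, was 6.8-fold higher, at 8.31 ± 0.021 against 5.55 ± 0.27 (SD, n = 3; limma, adjusted p = 7e-07). AMY1 (AT4G25000), a secreted alpha-amylase, was 7.56-fold lower, at 2.68 ± 0.16 against 5.6 ± 0.53 (SD, n = 3; limma, adjusted p = 1.7e-05).

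In the compound 3 comparison both measured type-A response regulators rose, RR16 (AT2G40670) by 2.62 on the log2 scale (SE 0.27, adjusted p = 2.3e-05). Of the 4 measured genes of cytokinin metabolism and transport 1 rose and 3 did not pass. The 1 that rose was UGT76C2 (AT5G05860), which attaches glucose to cytokinins, with a log2 change of 1.85 (SE 0.21). RR18 (AT5G58080), a type-B response regulator, changed by 1.90 (adjusted p = 0.016), but its call ended without compound 3 replicate 3 (1.38, adjusted p = 0.073), without DMSO control replicate 3 (1.79, adjusted p = 0.053) and with all transcript clusters tested (adjusted p = 0.067).

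The 3 Calvin cycle genes that rose with compound 3 were SBPASE, PRK (AT1G32060, phosphoribulokinase) with a log2 change of 1.93 and RCA (AT2G39730, Rubisco activase) with 0.93. The list's mean change was 1.87 (95% interval 1.68 to 2.07), with a camera adjusted p = 1.15e-05 and an adjusted p = 0.0523 with an estimated correlation. Of 6 genes of the photosystems and electron transport 4 rose and 2 did not pass, and 6 passed when adjusted over the list alone. Their mean change was 0.86 (camera adjusted p = 0.000241; adjusted p = 0.140 with an estimated correlation), and PSB27 (AT1G03600), a photosystem II assembly factor, rose by 1.29. Without 1 array in turn PSB27 kept its call in 6 of 6 fits, PSAN in 3, and PSAE-1 and ATPC1 in 2, and the calls of these 3 also ended when each array was centred on its median over all transcript clusters (adjusted p = 0.082, 0.128 and 0.135). Of 4 light-harvesting genes 1 rose, LHCB4.2 (AT3G08940) by 0.71 with a call kept in 1 of 6 such fits, and of 14 plastid-encoded genes 1 rose, matK by 0.60 with a call kept in 1 of 6. That centring ended both calls too (adjusted p = 0.128 and 0.197), and neither list passed (camera adjusted p = 0.371 and 0.179). The plastid-encoded rbcL, psbA, psaA, psaB, psbB and petB stood between 13.2 and 13.5 in control leaves, near the highest array value of 13.9, so their small differences do not show that their transcripts stayed the same. Of 6 chlorophyll synthesis genes 1 rose, CHLM (AT4G25080), the magnesium protoporphyrin methyltransferase, by 1.4. Of 2 chlorophyll breakdown genes NOL (AT5G04900), a chlorophyll b reductase, fell by 1.78 and SGRL (AT1G44000), a relative of the stay-green proteins, rose by 1.49.

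Genes of the cytosolic ribosome also rose with compound 3, 4 of 5 measured, and 4 when adjusted over the list alone. Their mean change was 0.87 (camera adjusted p = 0.00155; adjusted p = 0.172 with an estimated correlation), and RPL4A (AT3G09630) rose by 1.00. Without 1 array in turn RPL4A kept its call in 6 of 6 fits, RPL28A in 2, PGY1 in 1 and RPS21B in 0, and centring over all transcript clusters ended the calls of these 3 as well (adjusted p = 0.088, 0.127 and 0.142). Of 5 cell wall loosening genes 1 rose, EXPA8 (AT2G40610), an expansin, by 2.03, and 4 did not pass.

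In the list of dark and carbon starvation genes 3 of 5 fell with compound 3 and 2 did not pass, and 4 passed when adjusted over the list alone. LKR (AT4G33150), which breaks down lysine, changed by -1.72, and MCCB (AT4G34030), which acts in leucine breakdown, by -1.48. The other that fell, D2HGDH (AT4G36400), changed by -0.84 and kept its call in 2 of 6 fits without 1 array and not with all transcript clusters tested (adjusted p = 0.058). The list's mean change was -0.90 (camera adjusted p = 0.00182; adjusted p = 0.272 with an estimated correlation). Of 11 autophagy genes 5 fell, 6 did not pass, and 6 passed when adjusted over the list alone. ATG8G (AT3G60640), ATG8B (AT4G04620) and APG8A (AT4G21980), whose products coat autophagosomes, changed by -1.44, -1.40 and -1.2. The mean of the list was -0.74 (camera adjusted p = 4.43e-05; adjusted p = 0.172 with an estimated correlation).

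Of 6 genes of protein, nucleic acid and lipid breakdown 2 fell with compound 3, the vacuolar processing enzyme GAMMA-VPE (AT4G32940) by 1.66 and the cathepsin B-like protease CATHB3 (AT4G01610) by 1.33, and the list did not pass (camera adjusted p = 0.0501). Of 7 starch and sugar genes 3 fell, AMY1 among them, and the list did not pass either (camera adjusted p = 0.0550). In the list of senescence regulators and markers 1 of 6 passed, EEL (AT2G41070), a bZIP factor known from seed maturation, which rose by 0.92. The other tested lists had camera adjusted p between 0.110 and 0.969. Median, mean and test differed in sign for the senescence list (median -0.06, mean 0.06, test up), the jasmonate list (median -0.0086, mean 0.02, test down) and the phenylpropanoid list (median -0.03, mean 0.12, test up).

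Among genes with a symbol, NAI2 (AT3G15950), needed for endoplasmic reticulum bodies, rose most with compound 3, 65.3-fold, at 9.80 ± 0.13 against 3.77 ± 0.25 (SD, n = 3; limma, adjusted p = 2.2e-09). It was followed by ARR15, the expansin EXPA9 (AT5G02260) with a log2 change of 3.2, and NdhL (AT1G70760), a subunit of the chloroplast NADH dehydrogenase-like complex, with 2.95. CaS (AT5G23060), a thylakoid calcium-sensing protein, rose by 2.21 and MSRB8 (AT4G21840), a methionine sulfoxide reductase, by 2.49. GH3.17 (AT1G28130) and WES1 (AT4G27260), both of which join amino acids to auxin, changed by -3.84 and -2.71. WES1 was the 1 of 8 auxin response genes that passed. MT1B (AT5G56795), a metallothionein, changed by -3.63, the transcription factor bZIP44 (AT1G75390) by -3.34, CHAT (AT3G03480), which makes a green leaf volatile, by -3.28, and AAE16 (AT3G23790), an acyl-activating enzyme, by -3.23. COR47 (AT1G20440), a dehydrin, changed by -2.78 and was the 1 of 4 abscisic acid response genes that passed. DTX3 (AT2G04050), an efflux transporter, changed by -2.20 and was the 1 of 5 detoxification genes that passed. Of 4 reference genes TUB6 (AT5G12250), a tubulin, rose by 1.02 and 3 did not pass.

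Compound 3 changed 1957 of 16722 transcript clusters, of which 936 rose and 1021 fell, and 542 and 583 of these changed at least 2-fold. An unadjusted p under 0.05 was reached by 3866. With all transcript clusters tested 3360 were called, and with fry 13 lists passed against 5 with camera. All 3 treated arrays lay on the same side of all 3 control arrays for 26.4% of transcript clusters, against 10% by chance. Centring each array on its median over all transcript clusters brought the median change from 0.0097 to -0.15 and the split to 591 up and 1424 down, and quantile normalization applied again gave 800 up and 1278 down. Centring on the median over transcript clusters of 1 gene, chosen after seeing the data, gave 865 up and 1061 down, so the balance of rises and falls depends on the scaling.

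**Figure D2:**
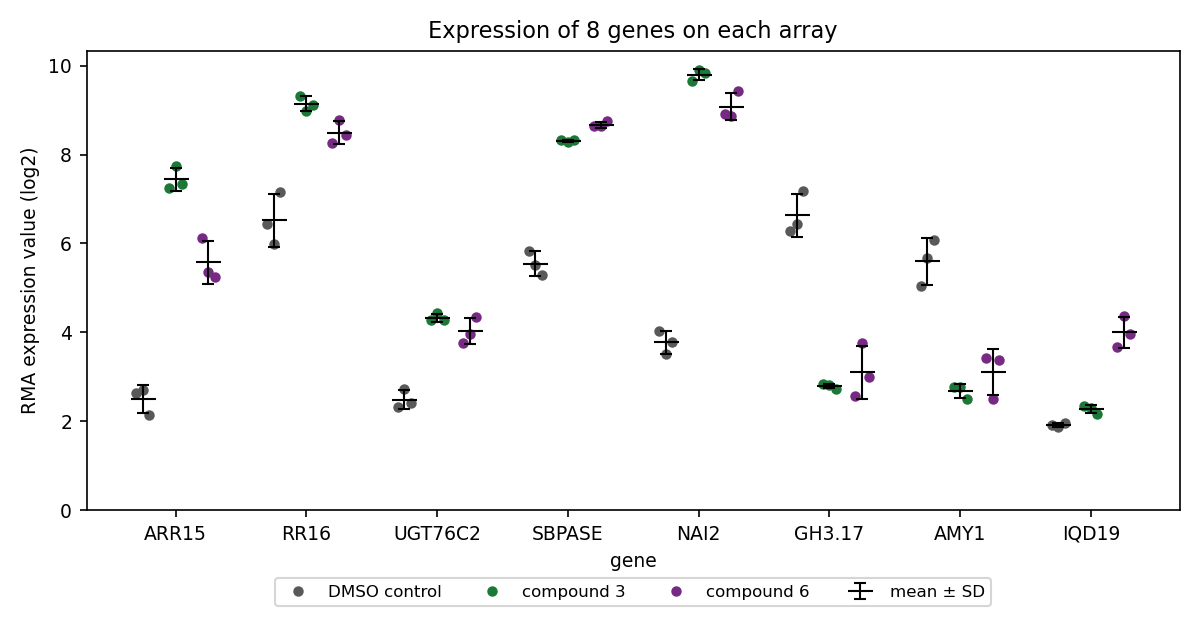
Log2 RMA value (vertical axis) of 8 genes (horizontal axis) on each of 9 arrays, with DMSO control in grey, compound 3 in green and compound 6 in purple; bars give the mean and SD of 3 arrays. ARR15 averaged 2.49 in control leaves, 7.45 with compound 3 and 5.57 with compound 6, while GH3.17 averaged 6.63, 2.79 and 3.1.

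Leaves kept with compound 6 had more transcript of all 3 measured Calvin cycle genes, 5 of 6 photosystem and electron transport genes and both measured type-A response regulators than control leaves, and less of 5 of 11 autophagy genes and 3 of 5 genes that darkness or sugar shortage induces. With an estimated correlation the Calvin cycle list kept its call (adjusted p = 0.0332), and the photosystem, autophagy and dark and carbon starvation lists lost theirs (adjusted p = 0.0866, 0.0901 and 0.183). SBPASE was 8.76-fold higher, at 8.68 ± 0.066 against 5.55 ± 0.27 (log2 value, SD, n = 3; limma, adjusted p = 7.7e-07). ARR15 stood at 5.57 ± 0.48 against 2.49 ± 0.31 in control leaves, 8.46-fold higher (SD, n = 3; limma, adjusted p = 7.7e-06). GH3.17 was 11.5-fold lower, at 3.1 ± 0.60 against 6.63 ± 0.48 (SD, n = 3; limma, adjusted p = 7e-06).

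Against control, compound 6 raised both measured type-A response regulators, RR16 by 1.97 on the log2 scale (SE 0.27, adjusted p = 0.00032). UGT76C2 rose by 1.54 (SE 0.21) and was the 1 of 4 genes of cytokinin metabolism and transport that passed. RR18 had a log2 change of 1.49 and did not pass (adjusted p = 0.060).

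All 3 measured Calvin cycle genes rose with compound 6, PRK by 1.79 and RCA by 1.13. The list's mean change was 2.02 (95% interval 1.83 to 2.21, camera adjusted p = 8.86e-07), and it kept its call with an adjusted p = 0.0332 with an estimated correlation. Of 6 photosystem and electron transport genes 5 rose, 1 did not pass, and 6 passed when adjusted over the list alone. The mean change was 0.91 (camera adjusted p = 2.63e-05; adjusted p = 0.0866 with an estimated correlation), and ATPC1 (AT4G04640), a subunit of the chloroplast ATP synthase, rose by 0.91. Without 1 array in turn ATPC1 kept its call in 6 of 6 fits and PSB27, PSBY and PSAN in 4. Of 4 light-harvesting genes LHCB4.2 rose by 0.86 and LHB1B2 (AT2G34420) by 0.82, with calls kept in 2 and 4 of 6 such fits, and 2 did not pass. None of 14 plastid-encoded genes passed with limma, with the same limit for the 6 near the highest array value, and neither of these lists passed (camera adjusted p = 0.156 and 0.136). Of 6 chlorophyll synthesis genes CHLM rose, by 1.1, and 5 did not pass. The calls of ATPC1, PSAN, LHCB4.2, LHB1B2 and CHLM ended when each array was centred on its median over all transcript clusters (adjusted p = 0.062, 0.096, 0.080, 0.112 and 0.058). SGRL rose by 1.96 and NOL changed by -1.32.

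Of 5 cell wall loosening genes 1 rose with compound 6, EXPA8 by 3.08, and 3 passed when adjusted over the list alone. The list's mean change was 0.97 (95% interval 0.80 to 1.13, camera adjusted p = 0.00490; adjusted p = 0.0901 with an estimated correlation). None of 5 cytosolic ribosome genes passed with limma over all genes, and 3 passed when adjusted over the list alone. The ribosome list's mean change was 0.53 (camera adjusted p = 0.0390, and 0.249 with an estimated correlation), and from 0.29 to 0.62 over the alternatives. Its call ended without compound 6 replicate 3 (0.45, adjusted p = 0.0891), without DMSO control replicate 1 (0.46, adjusted p = 0.0962) and with dim transcript clusters left out (adjusted p = 0.0636).

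Of 5 dark and carbon starvation genes 3 fell with compound 6, 2 did not pass, and 4 passed when adjusted over the list alone. Of the 3, D2HGDH changed by -0.91 and kept its call in 3 of 6 fits without 1 array. MCCB changed by -1.74 and LKR by -1.70, and the list's mean change was -1.0 (camera adjusted p = 0.00033; adjusted p = 0.183 with an estimated correlation). Of 11 autophagy genes 5 fell, 6 did not pass, and 9 passed when adjusted over the list alone. APG8A changed by -1.59 and ATG8B by -1.47, and both kept their calls in 6 of 6 fits without 1 array, while ATG8G did in 2 and ATG1A (AT3G61960) in 0. With all transcript clusters tested ATG1A did not pass either (adjusted p = 0.061). The list's mean was -0.81 (camera adjusted p = 3.24e-06; adjusted p = 0.0901 with an estimated correlation). Of 5 detoxification genes 1 fell, DTX3 by 2.3, and 2 passed when adjusted over the list alone. The detoxification list's mean change was -0.72 (camera adjusted p = 0.0315; adjusted p = 0.153 with an estimated correlation), and its call ended without DMSO control replicate 3 (-0.65, adjusted p = 0.0713).

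In the compound 6 comparison GAMMA-VPE fell by 0.95 and CATHB3 by 1.04, 2 of 6 genes of the breakdown list, which did not pass (camera adjusted p = 0.0638). Of 6 senescence regulators and markers 1 fell and 4 passed when adjusted over the list alone. The 1 was WRKY6 (AT1G62300), a senescence-associated transcription factor, by 0.77 (adjusted p = 0.014). The call of WRKY6 ended without compound 6 replicate 2 (-0.73, adjusted p = 0.059) and without DMSO control replicate 2 (-0.72, adjusted p = 0.052). STZ (AT1G27730), a zinc finger repressor, changed by -1.25 and was the 1 of 3 reactive oxygen genes that passed. The other tested lists had camera adjusted p between 0.119 and 0.934. Median, mean and test differed in sign for starch and sugar (median 0.18, mean -0.29, test down), cytokinin metabolism (median -0.0036, mean 0.27, test up), reactive oxygen (median 0.05, mean -0.36, test down) and the reference genes (median -0.25, mean 0.0017, test down).

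Among genes with a symbol, NAI2 again rose most with compound 6, 39.4-fold, to 9.08 ± 0.31 (SD, n = 3; limma, adjusted p = 1.3e-08). SBPASE, ARR15 and EXPA8 came next. NdhL rose by 2.82, CaS by 2.57, the endoglucanase GH9C2 (AT1G64390) by 2.13, HCF101 (AT3G24430), which inserts iron-sulfur clusters into photosystem I, by 2.13, and IQD19 (AT4G14750), a calmodulin-binding protein, by 2.09. MT1B changed by -3.27, bZIP44 by -2.75, WES1 by -2.71, CHAT by -2.52, AMY1 by -2.49, AAE16 by -2.21 and COR47 by -1.95. ChiC (AT4G19810), a chitinase, changed by -1.86. Of 4 reference genes TUB6 rose, by 1.11.

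Compound 6 changed 1728 of 16722 transcript clusters, of which 939 rose and 789 fell, and 561 and 455 of these changed at least 2-fold. An unadjusted p under 0.05 was reached by 3518. With all transcript clusters tested 3144 were called, and with fry 13 lists passed against 7 with camera. Treated and control arrays did not overlap for 24.6% of transcript clusters, against 10% by chance. Centring each array on its median over all transcript clusters brought the median change from -0.023 to -0.27 and the split to 551 up and 1569 down, and quantile normalization applied again brought the median to -0.14 and gave 731 up and 1147 down. Centring over transcript clusters of 1 gene gave 857 up and 872 down.

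**Figure D3:**
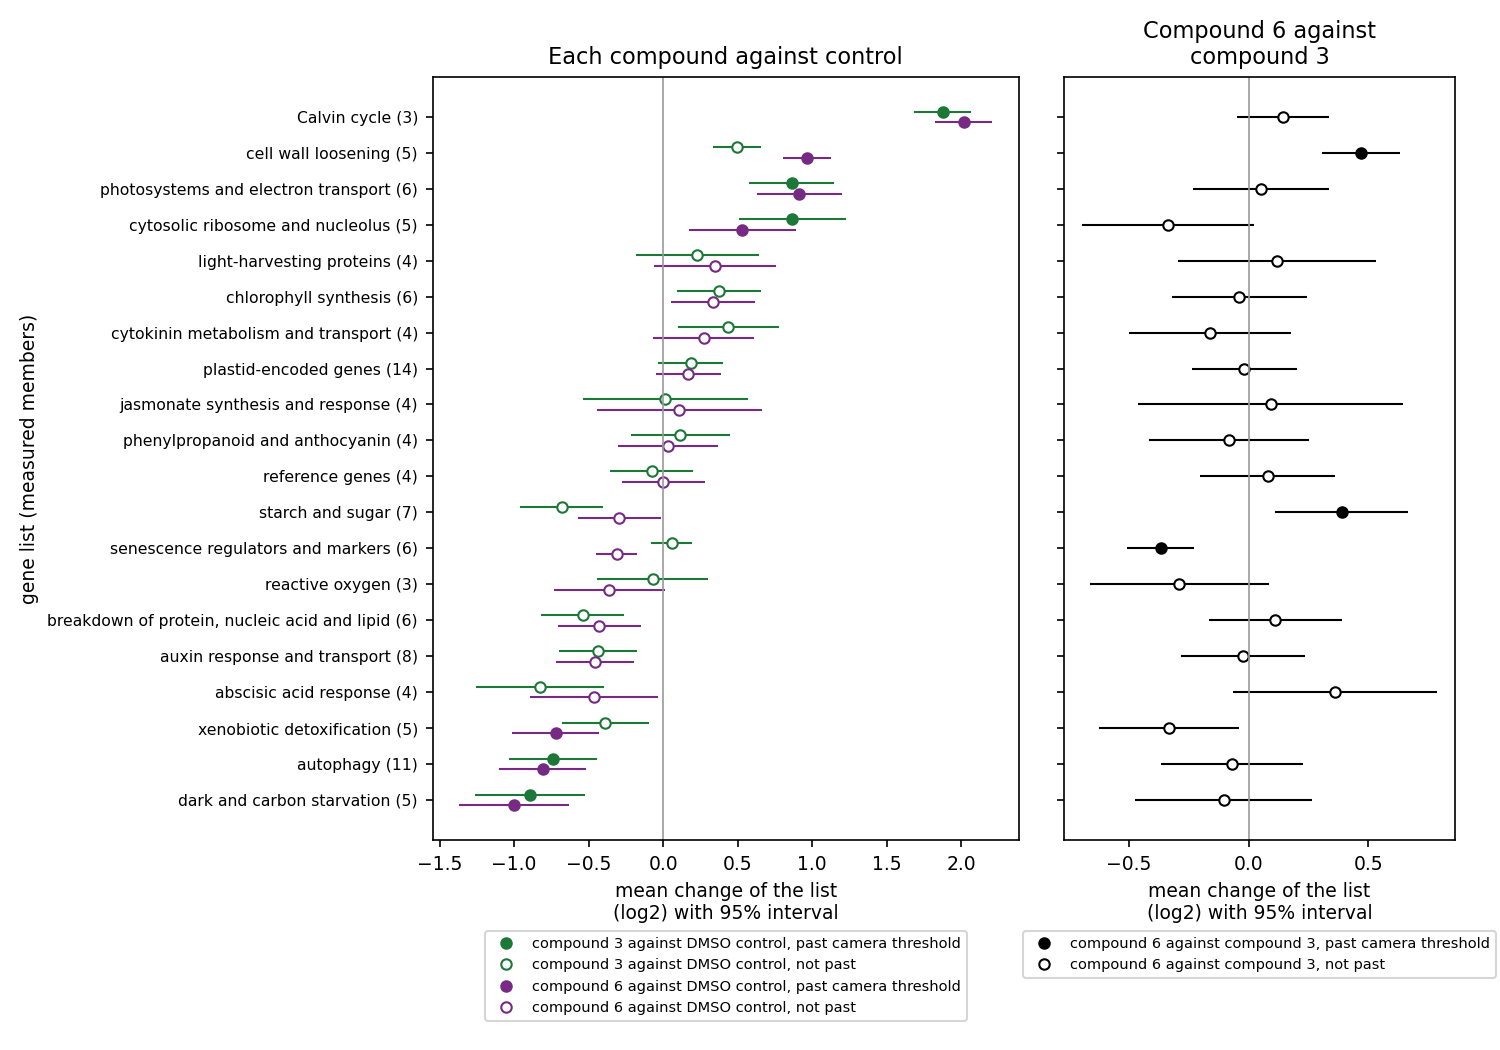
Mean log2 change of each tested gene list with its 95% interval (horizontal axis), for compound 3 and compound 6 against control and for compound 6 against compound 3; filled points passed camera at its preset correlation. The Calvin cycle list had means of 1.87 and 2.02 against control, and the dark and carbon starvation list -0.90 and -1.0.

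Many genes were called against control with both compounds. Handling of the control samples apart from the treated ones could also give shared changes, and it cannot be told apart from treatment here. Of genes with a symbol, NAI2, SBPASE, ARR15, NdhL and CaS were among the 10 that rose most with each compound, and GH3.17, MT1B, bZIP44, CHAT, AAE16, AMY1, CLE44 (AT4G13195), COR47 and WES1 among the 10 that fell most. CLE44, a peptide signal of vascular development, changed by -2.78 with compound 3 and -2.12 with compound 6. With both compounds 1202 transcript clusters were called, 1201 of them in the same direction, 595 up and 606 down. Independent lists of these sizes would share 52.6 up and 48.2 down, but both comparisons use the same control arrays and are not independent. Simulated unchanged groups gave a mean of 0 calls with both compounds, so the simulation offers no overlap to compare with. How much of the overlap comes from the shared controls was not measured. The 1 called in opposite directions was AT4G15680, chosen after its values were seen, with a log2 change of 1.44 for compound 3 (adjusted p = 0.00064) and -0.79 for compound 6 (adjusted p = 0.035). Its compound 6 call ended without compound 6 replicate 1 (-0.75, adjusted p = 0.104), compound 6 replicate 3 (-0.65, adjusted p = 0.148), DMSO control replicate 1 (-0.62, adjusted p = 0.144) and DMSO control replicate 2 (-0.85, adjusted p = 0.058), and with all transcript clusters tested (adjusted p = 0.067) or only the 2 groups compared in the fit (adjusted p = 0.064). A minimum log2 change of 1 also leaves it out by construction.

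Across transcript clusters, which are not independent replicates, the log2 changes of the compounds correlated at r = 0.82. Simulated unchanged groups that share a control group gave 0.42 ± 0.37 (SD over 100 simulations). With so wide a spread, r alone does not set the shared changes apart from what a shared control group produces. The covariance was 0.241 against a simulated 0.0308 ± 0.0339 (SD), a difference of 0.210. The sign was the same for 74.3% of transcript clusters against a simulated 65.2 ± 14.1% (SD), so this share lies within the simulated spread. Since 3 controls cannot be split into parts of at least 2, part of the excess in covariance may come from the shared controls. Among the 1202, the change was greater in size with compound 3 for 641 and with compound 6 for 561.

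**Figure D4:**
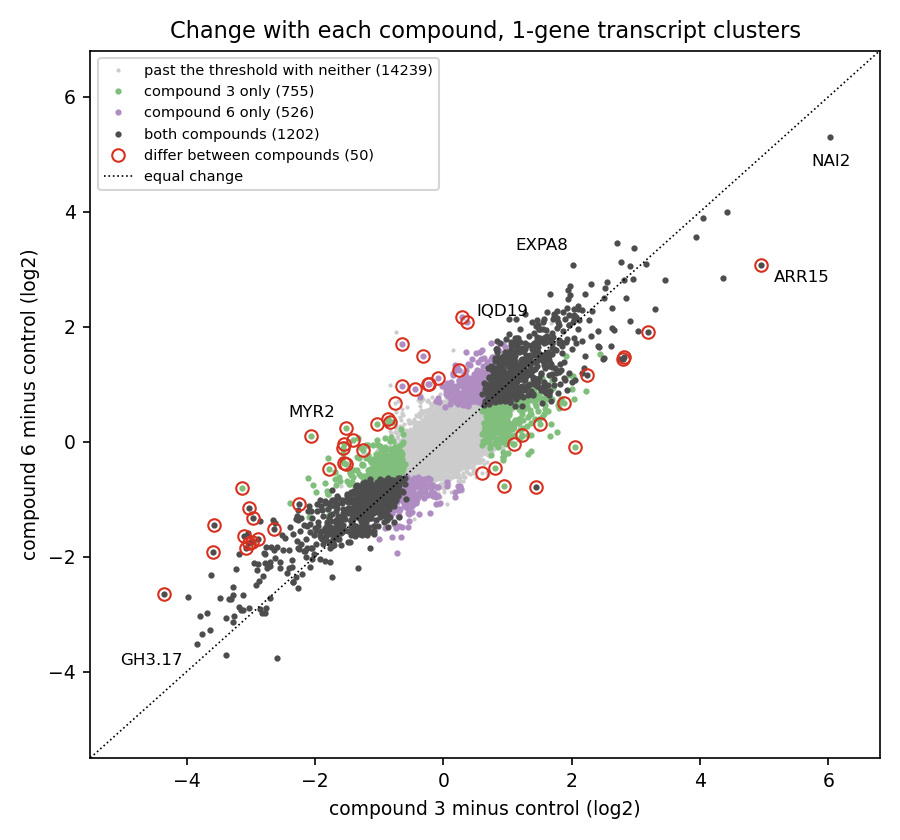
Log2 change with compound 6 (vertical axis) against log2 change with compound 3 (horizontal axis) for 16722 transcript clusters, coloured by the comparisons with control in which each was called; red circles mark the 50 that differed between compounds and the dotted line marks equal change. Of the 1202 called with both, 1201 changed in the same direction, and ARR15 lies below the line at 4.96 and 3.08.

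Between the compounds few genes were called. In the simulated compound 3 comparison 55% of genes changed by 1 on the log2 scale were called. A low number of calls therefore does not show that few genes differed. ARR15 was lower with compound 6 than with compound 3, by a log2 difference of -1.88 (95% interval -2.43 to -1.32, limma, adjusted p = 0.0065), and IQD19 was higher by 1.73 (1.29 to 2.17, adjusted p = 0.0030). IQD19 stood at 4.0 ± 0.35 with compound 6 against 2.27 ± 0.10 with compound 3 and 1.91 ± 0.052 in control leaves (SD, n = 3). Both calls held whichever of the 6 treated arrays was left out, and ended when all transcript clusters were tested (adjusted p = 0.085 for ARR15 and 0.053 for IQD19). MYR2 (AT3G04030), a MYB-related transcription factor, was higher with compound 6 by 1.75 (adjusted p = 0.0080), at 4.89 ± 0.33 against 3.14 ± 0.41 with compound 3 and 4.65 ± 0.34 in control leaves (SD, n = 3). The call of MYR2 ended without compound 6 replicate 2 (1.56, adjusted p = 0.053) and with all transcript clusters tested (adjusted p = 0.106).

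The other genes the rule named between the compounds had calls that ended in 5 of the 6 fits without 1 array, so that 1 fit kept each, with all transcript clusters tested (adjusted p from 0.106 to 0.127), and with the replicate number as a block (adjusted p from 0.057 to 0.073). That of BGLU40 also ended when each array was centred on its median over all transcript clusters (1.05, adjusted p = 0.053). APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, was higher with compound 6 by 1.26 (adjusted p = 0.023, from 0.034 to 0.095 without 1 array). SFP2 (AT5G27360), a sugar transporter-like protein, was higher by 1.22 (adjusted p = 0.027, from 0.044 to 0.129 without 1 array). BGLU40 (AT1G26560), a beta-glucosidase, was higher by 1.14 (adjusted p = 0.027, from 0.043 to 0.129 without 1 array), and EXPA9 was lower, with a difference of -1.28 (adjusted p = 0.027, from 0.046 to 0.120 without 1 array).

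Other genes of the cytokinin and photosynthesis groups did not pass between the compounds, and their intervals leave room for differences. The difference was -0.65 for RR16 (95% interval -1.23 to -0.07), -0.30 for UGT76C2 (-0.75 to 0.14) and 0.37 for SBPASE (-0.05 to 0.78). It was 0.83 for COR47 (adjusted p = 0.093), 0.72 for GAMMA-VPE (adjusted p = 0.134), 1.05 for EXPA8 (adjusted p = 0.159) and -1.04 for STZ (adjusted p = 0.154). The mean difference of the Calvin cycle list was 0.14 (95% interval -0.05 to 0.33), of the photosystem list 0.05 (-0.23 to 0.34) and of the autophagy list -0.07 (-0.36 to 0.23), and none of these passed. A p that misses the threshold does not show that the compounds act alike.

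Of 20 lists 3 passed camera between the compounds, and none kept its call with an estimated correlation. The 5 cell wall loosening genes were higher with compound 6 by a mean of 0.47 (95% interval 0.31 to 0.63, camera adjusted p = 0.0196; adjusted p = 0.230 with an estimated correlation), with no member called and 1 passing when adjusted over the list alone. Expansins as a family did not follow this list. The 13 genes with an EXPA symbol, a group chosen after seeing the data, had a median difference of -0.13 (camera adjusted p = 0.787). EXPA9, which is outside the list, was the 1 of them called, and it was lower. The 6 senescence regulators and markers were lower by a mean of -0.37 (-0.51 to -0.23, camera adjusted p = 0.0196; adjusted p = 0.230 with an estimated correlation), with no member called and 2 passing when adjusted over the list alone. Their greatest differences were -0.74 for SAG101 (AT5G14930), a regulator of leaf senescence and immunity (adjusted p = 0.103), and -0.50 for WRKY6 (adjusted p = 0.337). The 7 starch and sugar genes were higher by a mean of 0.39 (0.11 to 0.67, camera adjusted p = 0.0196; adjusted p = 0.333 with an estimated correlation), and APL3 was the 1 member called and the 1 passing when adjusted over the list alone. Without compound 6 replicate 1 no list passed (adjusted p = 0.0736 for each of the 3). Without compound 3 replicate 1 the cell wall call ended (0.42, adjusted p = 0.0515), and the starch call ended without compound 6 replicate 2 (0.35, adjusted p = 0.0919), without compound 3 replicate 2 (0.31, adjusted p = 0.0932) and with fry (adjusted p = 0.0885). Median and mean differed in sign for the plastid-encoded genes (median 0.0024, mean -0.02, test down) and the jasmonate list (median -0.04, mean 0.09, test up).

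Arrays of the compounds did not overlap for 16.0% of transcript clusters, against 10% by chance, and 1692 had an unadjusted p under 0.05. Between the compounds 50 of 16722 transcript clusters were called, 36 higher and 14 lower with compound 6. The count was 135 with array weights, 82 with dim transcript clusters left out, 29 with the replicate number as a block and 3 with all transcript clusters tested. Of the 50, 18 were called against control with both compounds, 20 with compound 3 alone, 10 with compound 6 alone and 2 with neither. Of the 36, 25 had fallen with compound 3, and of the 14, 13 had risen with it. Of the 755 called with compound 3 and not compound 6, 20 differed between the compounds, and of the 526 called with compound 6 and not compound 3, 10 did. The 95% interval of the difference lay within 1 log2 unit either side of 0 for 14336 transcript clusters (85.7%), with a median distance from centre to end of 0.49. Without 1 array in turn the count fell to between 20 and 29, from 26, 22 and 25 without compound 6 replicates 1, 2 and 3 to 29, 24 and 20 without compound 3 replicates 1, 2 and 3. Centring on the median over all transcript clusters gave 27 up and 19 down, and cyclic loess 39 up and 28 down.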

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

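The 3 tests of the unnamed transcript clusters, the test of neighbouring genes and the count of genes called lower without 1 treated array were chosen after the values they bear on had been seen, and the other tests in this part were set before their results.

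Transcript clusters that are not named here were left out of the main comparisons and differed between treated and control arrays. Of the 20927 unnamed clusters 1187 rose and 711 fell with compound 3, and 1308 rose and 532 fell with compound 6 (limma on all clusters, adjusted p under 0.05). In the run of 7079 clusters at the start of the table the median was higher than on control arrays by 0.34 with compound 3 and by 0.59 with compound 6 (0.37 without compound 6 replicate 2), and 163 and 365 of its clusters rose while 15 and 12 fell. A brighter background on treated arrays would also lift equally dim named clusters. Those moved by 0.0344, against 0.464 for the run, but the difference between run and named clusters varies over treated arrays with an SD of 0.383. Beside that spread even unmoved named clusters would not have decided the question, so no conclusion is drawn from the test. The array with the highest median, compound 6 replicate 2, is not the whole source, since 5 of the 5 other treated arrays lay above every control array. Handling of control and treated samples apart cannot be told apart from treatment, because 0 runs of the sample numbers in the labels hold both kinds, and a response of these transcripts to cytokinin stays open and untested.

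The change of 50 transcript clusters with 1 gene differed between the compounds, among them ARR15, with a difference of -1.88 on the log2 scale and no overlap between the groups' arrays. Over the 14 that were lower with compound 6 the median difference was -1.27. A uniformly smaller response to compound 6 would tie the difference to the mean change with a negative slope, and the bound set for it was -0.2. Over the 2259 transcript clusters called in the mean of both compounds the slope was -0.0862. Other splits of the treated arrays gave slopes from -0.0521 to 0.0209 (root mean square 0.0331). This argues against a uniform reduction as large as the bound, while a smaller one stays open. ARR15's own ratio was -0.467, which decides nothing, since ARR15 was flagged for this same difference. The median of the 14 stayed at -1.16 or lower without any 1 of the 6 treated arrays, which decides nothing, since the 14 were chosen on the same arrays. When all genes were refitted without 1 treated array in turn, at least 6 and at most 7 were called lower in each fit, which argues against 1 array as the source of all the calls, and for the calls that ended it stays open. Signal shared between near-identical neighbouring genes stays open for part of the set, since 4 of the 14 have another of them within 5 loci, and a difference in the action or uptake of the compounds was not tested.

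Each comparison was refitted for all 10 ways to split its 6 arrays into groups of 3. The true split was in each case the 1 of 10 that gave as many calls, and 10 splits are too few for a share under 0.05. Each other split mixes arrays of both true groups, so a real difference widens its spread and lowers its calls. The other splits therefore do not show what chance alone gives. For compound 3 against control the true split gave 1957 transcript clusters and 5 lists, against at most 0 transcript clusters and 3 lists in other splits. For compound 6 it gave 1728 transcript clusters and 7 lists, against at most 0 and 4. Between the compounds it gave 50 transcript clusters and 3 lists, against at most 0 and 1.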

How the results depend on the processing

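All alternatives were fixed before the data were examined except centring on the median over transcript clusters of 1 gene, chosen after seeing the data, which gave 1926, 1729 and 62 calls for compound 3, compound 6 and their difference. Of 119 called values of named genes none changed sign and 76 passed in every setting, and of 15 uncalled ones none changed sign and 6 passed in some setting. Over every gene the naming rule selects, 17 of 90 uncalled values changed sign in some setting. The largest of the 17 was 0.41 in size, and none of these values is given in the text. Testing all transcript clusters gave 3360 calls for compound 3, 3144 for compound 6 and 3 between the compounds, where more tests and the unnamed clusters enter the adjustment. A minimum log2 change of 1 left 1125 and 1016 by construction. Between the compounds leaving out dim clusters gave 82 calls and array weights 135, and the cause was not tested. Leaving out 1 array, which also leaves fewer samples, gave 1319 to 1633 calls for compound 3, 1227 to 1499 for compound 6, 20 to 29 between the compounds and 883 to 1045 shared calls, with 5 to 6, 6 to 8 and 0 to 4 lists. With an estimated correlation 0, 1 and 0 lists passed, a correlation taken from few genes and arrays. With fry, which does not compare a list with other genes, 13, 13 and 2 did. Over all settings 155 results of single lists kept their call, 25 lost it and none changed direction. The replicate number as a block gave 1648, 1453 and 29 calls, 5, 7 and 3 lists and 1010 shared calls. Same-numbered samples appeared to share only the number. Correlations of same-numbered arrays ran from -0.37 to 0.26, and 2 of 9 pairs exceeded 0.1. Only 3 of 9 arrays correlated best with an array of their own number. Arrays of different number ran from -0.32 to 0.51. The highest was compound 6 replicate 2 with DMSO control replicate 3, a resemblance across groups that the model does not include. Signal over background was not measured, so no limit of detection is given for dim genes. Beyond what the construction of a setting shows, the cause was not tested.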

Other observations

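The genes and families in this part were chosen after their values were seen. Neighbouring loci on chromosome 4 moved in different directions with the same compound. AT4G15690 changed by -1.84 with compound 3 (SE 0.25, adjusted p = 0.00021) and by -2.07 with compound 6, and AT4G15700 by -2.60 (SE 0.42) and -3.77. The adjacent AT4G15680 rose by 1.44 with compound 3 and stood at 2.38 ± 0.32 with compound 6 against 4.61 ± 0.13 with compound 3 (SD, n = 3; limma difference -2.23, adjusted p = 0.0015), and that difference passed in every alternative. AT4G15670 differed by -1.70 (adjusted p = 0.0080), though not without compound 6 replicate 1 (-1.62, adjusted p = 0.053) or compound 3 replicate 2 (-1.59, adjusted p = 0.056), nor with all transcript clusters tested (adjusted p = 0.105). AT4G15690 differed by -0.23 between the compounds (95% interval -0.76 to 0.29). Probes that read more than 1 of these neighbours were not examined.

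AT2G30540 was among the genes without a symbol that rose most, by 4.37 with compound 3 (SE 0.31, adjusted p = 8.9e-07) and by 2.85 with compound 6 (adjusted p = 6.1e-05). Its difference of -1.52 between the compounds had an adjusted p of 0.0571, from 0.0216 to 0.209 over the alternatives.

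Symbols grouped by their stem made 56 families with enough measured genes for camera. The ATG stem was lower with compound 3 (median -0.50 over 8 genes, adjusted p = 0.0366, 0.979 with an estimated correlation) and compound 6 (median -0.62, adjusted p = 0.0029, 0.677 with an estimated correlation), with 2 of 8 called in each. The EXPA stem was higher with compound 3 (median 0.27 over 13 genes, 2 called, adjusted p = 0.0456, 0.979 with an estimated correlation), and with compound 6 it did not pass (median 0.086, 2 called, adjusted p = 0.0809). The IQD stem held 17 genes, of which 4 rose with compound 6 and none fell, and it did not pass (camera adjusted p = 0.0894). With compound 3, 3 rose and none fell (camera adjusted p = 0.724). Between the compounds the stem did not pass either (camera adjusted p = 0.732).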
